A study of Arabidopsis thaliana with 8 samples.

How the data were processed

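RNA from rosette leaves of wild type (Columbia) and dor mutant Arabidopsis plants, watered or droughted, was hybridised as biotin-labelled cRNA made from 5 µg of RNA to 8 Affymetrix ATH1 arrays, 2 per group. The deposited intensity values were made by the authors with GCOS and MAS5, whose versions are not stated, as 1 linear signal per probe set and array. On each array as deposited, the mean intensity over probe sets after trimming 2% at each end lay at 500. Detection calls were not analysed here, and 0 columns of the table were left unmapped to a group.

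Signals under 1 were set to 1, which applied to 399 values, of which 3 lay in tested probe sets, and log2 was taken with the authors' scaling kept. A probe set was tested when at least 2 arrays were at or above the 40th percentile of their own array, and the 64 Affymetrix control probe sets were left out, which gave 15523 tested probe sets. Probe sets were matched to genes through a probe table, and names were taken from a RefSeq gene table. Of the 22810 probe sets 13513 stood for 1 gene, 503 for several, and 8730 were not listed. Of those with 1 gene 13436 matched the gene table and 77 did not. Of the tested probe sets 8495 stood for 1 gene. No coordinates are given, since the files name no genome build.

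Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets of each comparison and a threshold of 0.05. A model of 4 group means, with 4 residual degrees of freedom, gave the drought response in wild type and in dor, the genotype difference under control watering and under drought, and the difference of the drought responses. An additive model of condition and genotype, with 5 residual degrees of freedom, gave the genotype difference over both conditions. These comparisons, the filters, the 28 gene lists, the rule for named genes and the first set of alternatives were set before the data were examined. The additive drought response over both genotypes was added after the data were seen.

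The 28 lists hold 450 loci, of which 58 have a named probe set and 52 a tested one, and 8 lists with at least 3 tested members were tested. Where several probe sets stood for 1 gene, the one with the highest mean was used. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. The list of cytosolic ribosomal proteins had been planned from gene descriptions, which the tables do not hold, so it was written from locus identifiers after the data were seen. The list of plastid-encoded genes and 34 families of genes with a shared symbol and at least 5 tested members were also added after the data were seen.

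Genes were named by rule: DOR and NCED3, then for each comparison the 4 largest rises and 4 largest falls among called probe sets that stand for 1 gene and whose compared groups do not overlap. From each list the rule takes up to 2 called members in the wild type and dor drought comparisons and 1 in the others. For the added drought comparison 2 per list were named. Where no member of a list was called, its values are given without a verdict. For named genes the drought differences were also computed with each signal under the 40th percentile of its array raised to that percentile, a step added after the data were seen and without a test.

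The alternatives set at that time were quantile normalization, median centring, an offset of the 10th percentile of the signals, no filter, a filter at the 60th percentile and no intensity trend. Further ones were the replicate number or the wording of the RNA extraction label as a block, an added threshold of 1 on the log2 change, only the 4 arrays compared, an estimated correlation for lists, and leaving out each array in turn. Added after the data were seen were a random block of condition and replicate number (duplicateCorrelation), a fixed replicate block within condition, and leaving out both controls of replicate 1.

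The pipeline was tested on simulated data with 200 changed probe sets. For the drought response in wild type it recovered 4.48% of changes of 2 log2 units, 70.1% of 4 and 93.9% of 8, with 3 false calls among 15323 unchanged probe sets. For the drought response in dor it recovered 1.49%, 46.3% and 95.5% of these sizes, with 6 false calls. For the genotype difference over both conditions the shares were 22.4%, 82.1% and 93.9% with 4 false calls, and for the drought response over both genotypes 26.9%, 88.1% and 98.5% with 7. The simulated arrays varied independently, while the real arrays of one condition and replicate number deviated together. These shares and false calls therefore need not hold for the real data, least of all for the 2 additive comparisons. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.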

Results

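Rosette leaf RNA of Arabidopsis thaliana was measured on 8 Affymetrix ATH1 arrays, which report 1 signal for each of 22810 probe sets. The arrays form 4 groups of 2 biological replicates: wild type plants of the Columbia accession and plants of the dor mutant, a T-DNA insertion line in the same background. Each genotype was either watered for 34 days (control) or watered for 24 days and then left without irrigation for 10 days (drought). The design asks how the leaf transcriptome responds to drought in each genotype and whether the mutant differs from wild type with or without water. Each comparison of groups rests on 2 arrays per side, and this number limits the precision of every value below. Changes are log2 differences of group means with the standard error of the limma fit.

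DOR (AT2G31470), the F-box gene the mutant is named after, gave very low signals on all arrays. Its probe set read 7.0 and 5.0 in wild type control replicates 1 and 2, 3.1 and 5.2 in wild type drought, 3.7 and 21.4 in dor control, and 2.3 and 3.7 in dor drought. These signals lie below the 40th percentile of their arrays, which ranged from 59.5 to 90.8, so the gene was not tested and its level gives no check of the genotype labels.

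The arrays also split by replicate number. The geometric mean signal of 12 bacterial poly-A spike-in probe sets, RNAs added during labelling, was at least 337 on the 4 arrays of replicate 1 and at most 104 on those of replicate 2. The median signal was 97.4 to 120.5 on the arrays of replicate 1 and 163.4 to 170.8 on those of replicate 2. The ratio of 5 prime to 3 prime actin signal, a measure of RNA integrity and labelling, was 0.229 and 0.245 in the wild type and dor controls of replicate 1 and 0.366 to 0.575 on the other 6 arrays. The ratio of middle to 3 prime ubiquitin signal, a measure of the same kind, was 0.430 to 0.632 on the drought arrays and 0.174 to 0.405 on the control arrays. The 5 prime to 3 prime ratio of GAPDH overlapped between the conditions, at 0.799 to 1.09 in drought and 0.847 to 1.03 in control.

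**Figure D1:**
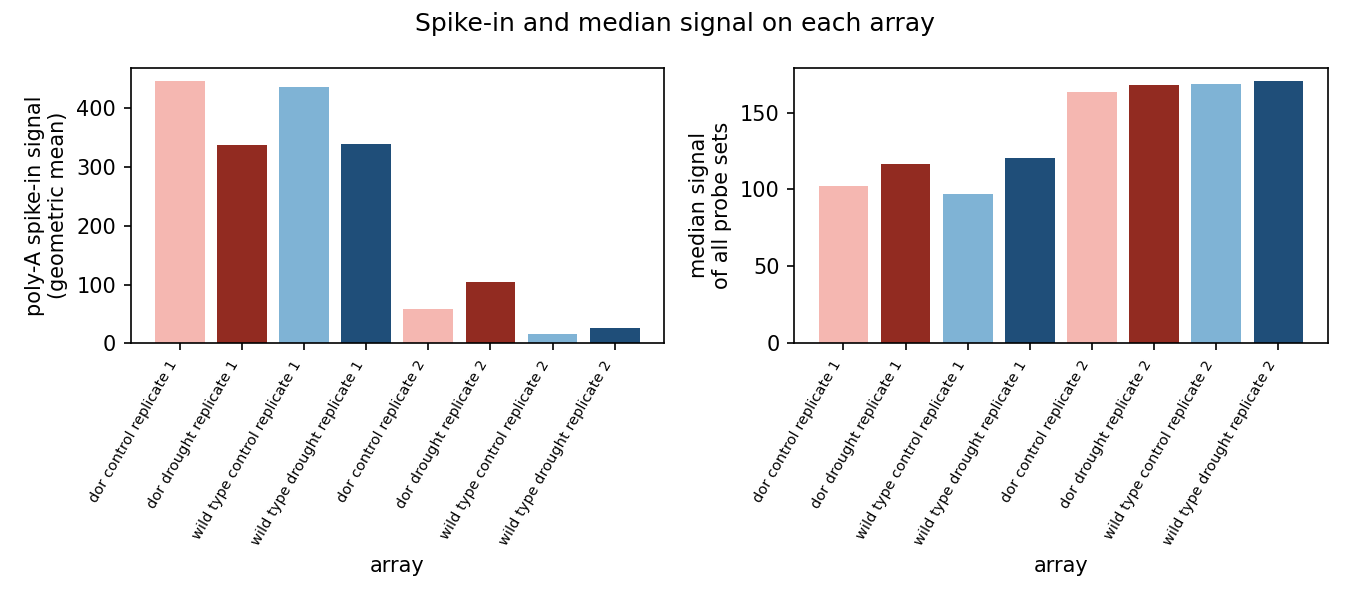
Geometric mean signal of 12 poly-A spike-in probe sets (left axis panel) and median signal of all probe sets (right axis panel), in deposited signal units, with 1 bar per array coloured by group. All 4 spike-in bars of replicate 1 lie at or above 337 and all 4 of replicate 2 at or below 104.

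In wild type, 1 of 15523 tested probe sets passed the test for drought, and none of the genes named in this paragraph did. SAG29 (AT5G13170, the sugar transporter SWEET15, named for its rise in senescing leaves) stood at 5.5 and 4.5 in the control arrays and 591 and 6234 in drought, a log2 difference of 8.59 ± 1.11 with an adjusted p of 0.125. HIS1-3 (AT2G18050), a linker histone known for induction by drought, differed by 7.07 ± 1.67 (adjusted p = 0.293), and the antenna gene LHCB4.3 (AT2G40100) by -2.37 ± 0.99 (adjusted p = 0.502). The control signals of SAG29, and 1 of the 2 of HIS1-3, lay under the 40th percentile of their arrays, so the size of these differences depends on background. With signals under that percentile raised to it, they were 4.72 for SAG29 and 5.68 for HIS1-3. Of 15523 tested probe sets 1 was higher and 0 were lower at an adjusted p under 0.05, and 1482 had an unadjusted p under 0.05, where chance gives 776. The 1 called probe set has no gene name in the annotation used here and was looked at after its values were seen. Its signal was 314 and 268 in the controls and 16262 and 26259 in drought. It rose by 6.15 ± 0.50 (adjusted p = 0.0178). The call was lost with median centring, with the wording of the RNA extraction label as a block, without the intensity trend, and without the controls of replicate 1. It was also lost without 6 of the arrays taken singly, that is, without any array except the dor controls.

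Among the gene lists, the drought and abscisic acid (ABA) effector genes, which code for dehydrins, other late embryogenesis abundant (LEA) proteins and related products, had a median difference of 2.75 in wild type over 8 tested members, 6 of them positive. None was called over all probe sets, and 5 were higher and 1 lower when adjusted over the list alone. Their shift passed camera with a preset correlation (adjusted p = 0.0106) but not with an estimated one (adjusted p = 0.463). The shift rested on single arrays: its adjusted p was 0.101 without wild type control replicate 1 and 0.138 without wild type drought replicate 2. The 6 expansin and xyloglucan enzyme genes, which loosen cell walls, had a median of -1.55 with all 6 negative and 1 lower when adjusted over the list alone (camera adjusted p = 0.00442, and adjusted p = 0.192 with an estimated correlation). Their camera adjusted p was 0.0966 without wild type drought replicate 2. The 7 photosystem and antenna genes had a median of -0.70 with all 7 negative (camera adjusted p = 0.0285, and adjusted p = 0.664 with an estimated correlation). This shift was lost after quantile normalization (adjusted p = 0.155), after median centring (adjusted p = 0.110), without the intensity trend (adjusted p = 0.0574), without wild type control replicate 1 (adjusted p = 0.883) and without wild type drought replicate 2 (adjusted p = 0.167). Within replicate 1 the median drought differences of these 3 lists, in the order effectors, wall enzymes and photosystems, were 3.05, -2.22 and -0.85, and within replicate 2 they were 1.46, -2.19 and -0.36. The photosystem genes also differed between the watered arrays, with a median of -0.88 in wild type and -0.90 in dor for control replicate 2 minus replicate 1. The tested members are only a part of each list. They are 8 of 34 effector, 6 of 22 wall enzyme, 7 of 42 photosystem and antenna, 3 of 18 Calvin cycle and 3 of 15 guard cell genes. List values here and below describe these members and not the whole lists.

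**Figure D2:**
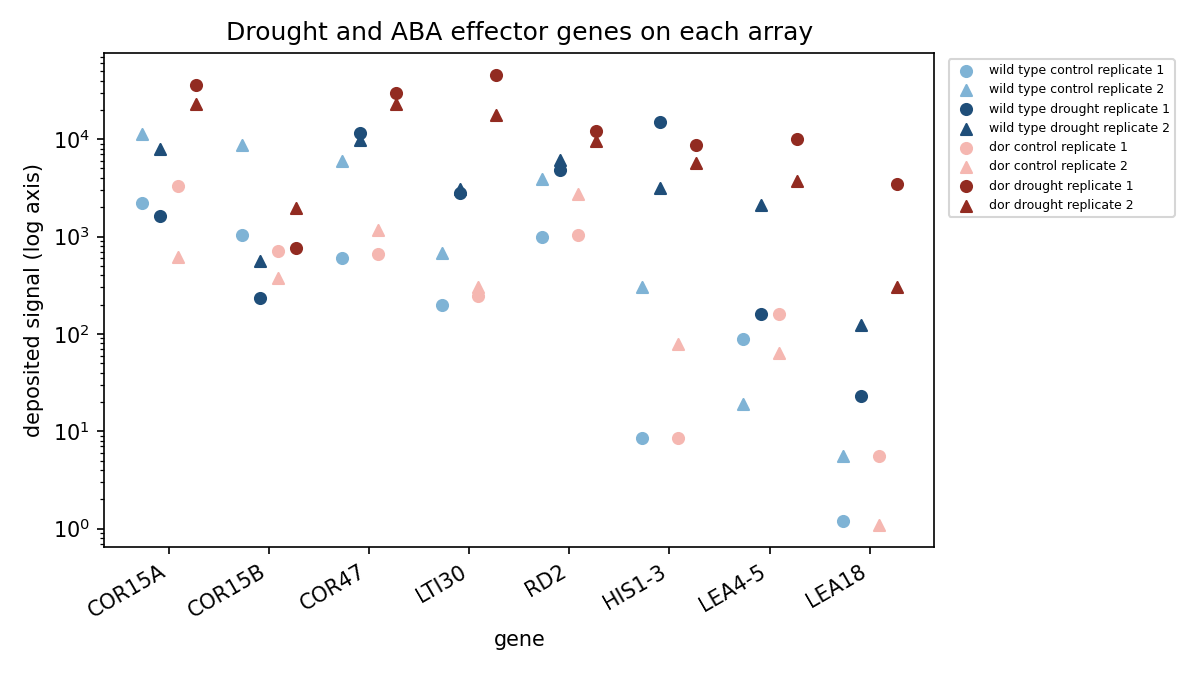
Deposited signal on a log axis of the 8 tested drought and ABA effector genes, with 1 point per array, colour for the group, circles for replicate 1 and triangles for replicate 2. LTI30 stands at 17566 and 45119 in dor drought against 2819 and 3065 in wild type drought, and COR15A at 11241 in wild type control replicate 2 against 2229 in replicate 1.

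In dor, drought raised 49 probe sets and lowered 39, and 46 of these 88 stand for 1 named gene. By fitted value the largest rises among those with 1 named gene were AT3G17520, which codes for a LEA family protein (10.57 ± 1.28, adjusted p = 0.0193), and AT5G39520 (9.06 ± 0.67, adjusted p = 0.00500). Next came AT1G16850 (8.69 ± 1.38, adjusted p = 0.0420) and the organic cation transporter gene OCT1 (AT1G73220, 8.57, adjusted p = 0.0274). The dehydrin LTI30 (AT3G50970) rose from 243 and 303 to 45119 and 17566, a change of 6.70 ± 0.73 (adjusted p = 0.0139), and SAG29 rose by 7.86 ± 1.11 (adjusted p = 0.0285). The largest falls among them by fitted value were AT5G03350, which codes for a legume lectin family protein (-8.70 ± 0.69, adjusted p = 0.00500), and the glutaredoxin family gene AT1G06830 (-8.44 ± 1.05, adjusted p = 0.0205). Next came the lipid transfer family gene AT2G10940 (-8.09 ± 1.05, adjusted p = 0.0225) and AT1G22690 (-7.59 ± 0.93, adjusted p = 0.0205). The expansin EXPA8 (AT2G40610) fell from 2665 and 849 to 48.2 and 8.2, a change of -6.24 ± 1.04 (adjusted p = 0.0499). Apart from LTI30, these genes lay under the 40th percentile of their arrays on both control arrays (rises) or both drought arrays (falls). The sizes and order of their changes therefore depend on background. With such signals raised to the percentile the rises were 6.31 for AT3G17520, 7.04 for AT5G39520, 6.16 for AT1G16850, 3.60 for OCT1 and 5.41 for SAG29. The falls were then -6.95 for AT5G03350, -5.49 for AT1G06830, -5.69 for AT2G10940, -5.49 for AT1G22690 and -4.33 for EXPA8. The EXPA8 call was lost in 13 of 19 other settings, with any 1 of the 8 arrays left out among them. Of the 19 settings, the call of AT1G16850 was lost in 10, OCT1 in 7, SAG29 in 6, AT3G17520 in 5, AT1G06830 and AT2G10940 in 4, LTI30 and AT1G22690 in 3, and AT5G03350 and AT5G39520 in 2. The calls of AT3G17520 and AT1G16850 were among those lost with condition and replicate number as a random block, a setting added after the data were seen.

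The effector genes had a median drought difference of 5.41 in dor with all 8 positive. LTI30 was the 1 member called over all probe sets, and 7 were higher when adjusted over the list alone. Camera gave an adjusted p of 4.56e-08 with the preset correlation and the estimated one gave an adjusted p of 0.131. All 7 tested photosystem and antenna genes were negative with a median of -2.08. Of these 0 were called over all probe sets but 7 were lower when adjusted over the list alone (camera adjusted p = 1.76e-06, and adjusted p = 0.189 with an estimated correlation). The 3 Calvin cycle genes RCA, PRK and SBPASE had a median of -2.43 with all 3 negative and 2 lower when adjusted over the list alone (camera adjusted p = 0.00761, and adjusted p = 0.242 with an estimated correlation). The expansin and xyloglucan list had a median of -3.16 with all 6 negative, of which EXPA8 was called and 2 were lower when adjusted over the list alone (camera adjusted p = 0.000195, and adjusted p = 0.122 with an estimated correlation). The 3 guard cell markers passed camera at an adjusted p of 0.0442 (adjusted p = 0.189 with an estimated correlation) through AT1G22690 alone. The transcription factor gene FMA and the ion exchanger gene CHX20 differed by -0.41 and -0.17. The shift of this list was lost with the replicate number as a block (adjusted p = 0.0727), without the intensity trend (adjusted p = 0.0513), with the stricter filter (adjusted p = 0.0550) and without either array of dor replicate 2 (adjusted p = 0.110 and 0.107) or either wild type drought array (adjusted p = 0.0553 and 0.0548). The rotation test fry gave adjusted p values in dor of 0.0123 for the effector, 0.0414 for the photosystem, 0.108 for the Calvin cycle and 0.00356 for both the wall enzyme and the guard cell list. In wild type fry gave 0.0212 for both of the last 2, 0.229 for the effector, 0.591 for the photosystem and 0.866 for the Calvin cycle list. Within replicate 1 the medians of the effector, photosystem, Calvin cycle, wall enzyme and guard cell lists were 5.72, -3.22, -3.94, -3.44 and -0.02. Within replicate 2 they were 5.53, -1.003, -0.92, -2.06 and -1.12.

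limma made the 88 calls in dor from 2433 probe sets with an unadjusted p under 0.05. The count was 0 without dor drought replicate 1, 5 without dor control replicate 1, 57 without wild type drought replicate 1, 56 without wild type drought replicate 2, 153 after quantile normalization and 35 with the extraction wording as a block. It was also 0 without the controls of replicate 1, the pair with the low actin ratio. With the replicate number as a block the count was 96.

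**Figure D3:**
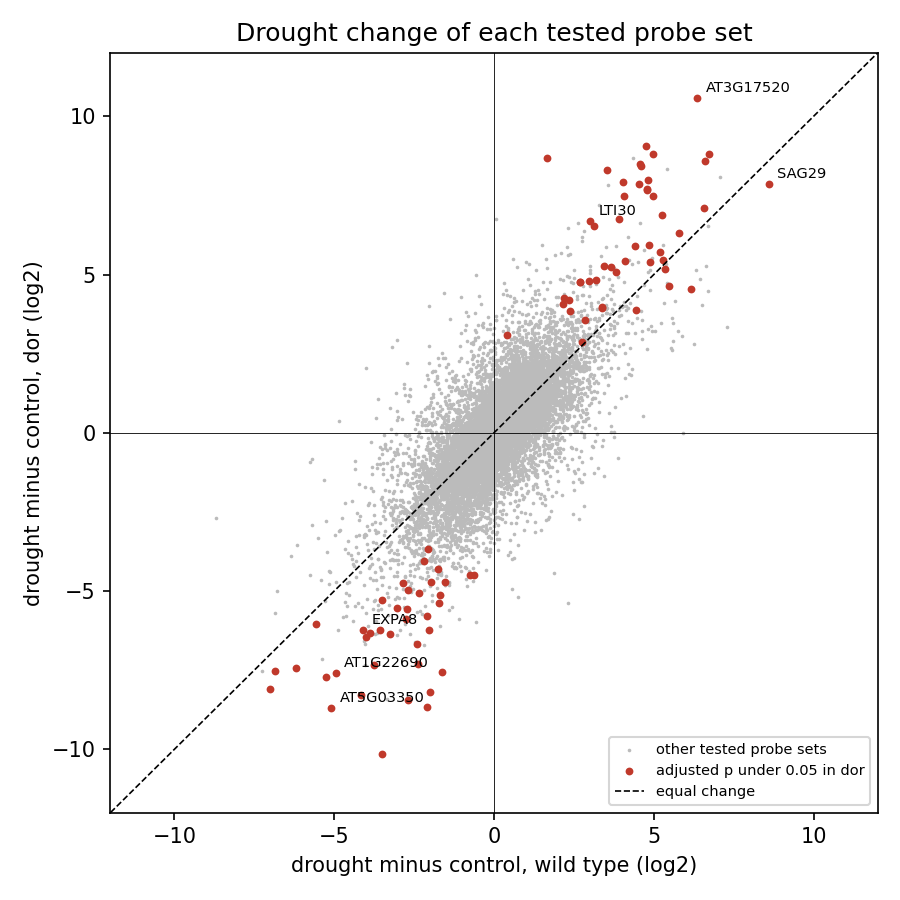
Log2 difference of drought minus control in wild type (horizontal axis) and in dor (vertical axis) for each of the 15523 tested probe sets, with those past an adjusted p of 0.05 in dor in red and a dashed line of equal change. All 88 red points have the same sign in both genotypes, and 83 lie farther from 0 in dor, which choosing the points by their test in dor favours.

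The drought differences of the genotypes went together. They share no array, but arrays of both genotypes with one condition and replicate number deviated together (r = 0.402 under drought and 0.594 under control watering). These shared deviations enter both differences, so their agreement is not that of independent experiments. All 88 probe sets called in dor had the same sign in wild type, and 79 of them also had an unadjusted p under 0.05 there. Across the tested probe sets, which are not independent, the differences correlated at r = 0.735 between genotypes. The correlation between genotypes was 0.732 within replicate 1 and 0.428 within replicate 2, while the replicates of 1 genotype correlated at 0.290 in wild type and 0.494 in dor. An additive comparison of the 4 drought with the 4 control arrays was chosen after the data were seen. SAG29 rose in it (8.22 ± 0.74, adjusted p = 0.00316), as did AT3G17520 (8.47, adjusted p = 0.00795) and OCT1 (7.58 ± 0.85, adjusted p = 0.00469). Among the effector genes HIS1-3 rose by 7.58 ± 1.13 (adjusted p = 0.0126) and LEA18 (AT2G35300) by 6.52 ± 1.35 (adjusted p = 0.0304). With signals under the 40th percentile raised to it, these 5 rises were 5.06, 4.79, 2.63, 6.12 and 2.01, in the order given. The zinc finger repressor STZ (AT1G27730) rose by 3.03 ± 0.61 (adjusted p = 0.0289). The ABA glucosyltransferase gene UGT71B6 (AT3G21780) rose by 3.52 ± 0.76 (adjusted p = 0.0339) and the small heat shock gene AT5G37670 by 2.37 ± 0.47 (adjusted p = 0.0272). AT2G10940 changed by -7.56 ± 0.72 (adjusted p = 0.00355), AT3G16670 by -7.19 ± 0.69 (adjusted p = 0.00355), AT5G03350 by -6.90 ± 0.74 (adjusted p = 0.00469) and AT3G05730 by -6.82 ± 0.73 (adjusted p = 0.00469). With raised signals these 4 were -6.35, -6.46, -6.02 and -6.37, and the rise of UGT71B6 was 2.1005. Smaller falls were those of LHCB4.3 by -3.10 ± 0.70 (adjusted p = 0.0369), the thylakoid ascorbate peroxidase gene TAPX (AT1G77490) by -2.35 ± 0.57 (adjusted p = 0.0462) and EXPA16 (AT3G55500) by -2.41 ± 0.58 (adjusted p = 0.0463). EXPA16 lost its call in 12 of 18 other settings, TAPX in 11, LHCB4.3 in 9, and STZ, LEA18, UGT71B6 and AT5G37670 in 8 each. The other genes given with a value in this comparison lost theirs in at most 2. Of the 8 effector genes 7 were positive and 5 called, with a median of 4.27 over the list (camera adjusted p = 0.000295, and adjusted p = 0.299 with an estimated correlation). All 6 wall enzyme genes were negative and 2 were called, with a median of -2.52 (camera adjusted p = 0.000335, and adjusted p = 0.0885 with an estimated correlation). All 7 photosystem genes were negative and 1 was called, with a median of -1.17 (camera adjusted p = 0.000308, and adjusted p = 0.315 with an estimated correlation). Every one of these member calls was lost with condition and replicate number as a random block. With fry these 3 lists had adjusted p values of 0.0230, 0.0604 and 0.00348, in the order effectors, photosystems and wall enzymes. These camera and fry values treat the wild type and dor arrays of one condition and replicate number as independent. The lists of this comparison were not tested with the random block.

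That comparison called 902 probe sets, 441 higher and 461 lower, but it counts the wild type and dor arrays of one condition and replicate number as independent, and these deviated together. With condition and replicate number as a random block, which gave a consensus correlation of 0.608, 12 calls were left, 9 higher and 3 lower. SAG29, AT2G10940, AT3G16670 and AT3G05730 were among the 12, and the other genes given with a value in this comparison were not. Leaving out 1 array gave 171 calls without dor drought replicate 1, 207 without dor control replicate 1 and 208 without wild type control replicate 1. It gave 293 without dor drought replicate 2, 320 without wild type drought replicate 1 and 1543 without wild type control replicate 2. Without the controls of replicate 1 there were 12 calls.

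Between the watered genotypes no probe set passed the test. limma gave 0 calls at an adjusted p under 0.05 and 71 probe sets at an unadjusted p under 0.05, where chance gives 776. Models that allow for the shared deviations of arrays with one replicate number, added after the data were seen, also gave 0 calls in limma. At an unadjusted p under 0.05 they gave 626 with the random block and 435 with a fixed replicate block within condition. LTI30 differed by -0.43 ± 0.73 and EXPA8 by 0.00 ± 1.04 between dor and wild type. The effector genes had a median of -0.71, with 7 of 8 negative (camera adjusted p = 0.0459, adjusted p = 0.784 with an estimated correlation, and 0.915 with fry). This shift was lost with the replicate number as a block (adjusted p = 0.109), without the filter on low signal (adjusted p = 0.119) and without the intensity trend (adjusted p = 0.0928). It was also lost without dor control replicate 1, dor control replicate 2, wild type drought replicate 1 or wild type drought replicate 2 (adjusted p = 0.0849, 0.564, 0.0802 and 0.0773). The median turned to 0.49 without wild type control replicate 2, the array with the high COR15A signal.

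Under drought, lists of genes differed between dor and wild type by camera with the preset correlation, but not with an estimated one or by fry, and limma called no single gene. LTI30 was at 45119 and 17566 in dor and 2819 and 3065 in wild type (3.26 ± 0.73, adjusted p = 1.0). AT1G06830, a glutaredoxin family gene, was at 8.1 and 11.5 against 452 and 477 (-5.59 ± 1.05, adjusted p = 1.0), a difference of -2.64 with the dor signals raised to the 40th percentile. limma gave 0 calls and 492 probe sets at an unadjusted p under 0.05, where chance gives 776. The median of the effector list was 2.37 with all 8 positive (camera adjusted p = 1.35e-07, and adjusted p = 0.193 with an estimated correlation), and 1 member was higher when adjusted over the list alone. The photosystem list had a median of -1.13 with all 7 negative (camera adjusted p = 2.71e-06, and adjusted p = 0.197 with an estimated correlation). The Calvin cycle list had -1.88 with all 3 negative (camera adjusted p = 0.00103, and adjusted p = 0.197 with an estimated correlation), and the wall enzyme list -1.16 with all 6 negative (camera adjusted p = 0.0121, and adjusted p = 0.193 with an estimated correlation). For these 4 lists fry gave adjusted p values of 0.204, 0.204, 0.212 and 0.1003. Within replicate 1 these 4 medians were 2.84, -1.65, -2.72 and -1.43, and within replicate 2 they were 1.25, -0.46, -0.67 and -0.97. The Calvin cycle shift was lost without dor drought replicate 1 (median -0.48, adjusted p = 0.0756) and the wall enzyme shift without wild type drought replicate 1 (median -0.92, adjusted p = 0.120) and without the filter on low signal (median -0.59, adjusted p = 0.103). The random block of condition and replicate number, added after the data were seen, called 22 probe sets, 1 higher and 21 lower in dor, and AT1G06830 was one of 9 with 1 named gene. A fixed block of replicate number within condition, also added then, called 0 in limma, with 1617 at an unadjusted p under 0.05.

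The difference of the drought responses asks whether drought moved a gene more in dor than in wild type. It had 0 calls in limma and 185 probe sets at an unadjusted p under 0.05, where chance gives 776. The 88 calls in dor against 1 in wild type therefore do not show that any gene responded differently. With fewer small p values than chance gives, the 0 calls do not show equal responses either. LTI30 differed by 3.69 ± 1.03 and AT1G06830 by -5.77 ± 1.49, both at an adjusted p of 1.0. As lists, the effector genes had a median difference of 3.05 with all 8 positive (camera adjusted p = 8.64e-10, and adjusted p = 0.190 with an estimated correlation). The photosystem genes had -1.46 (camera adjusted p = 2.28e-06, and adjusted p = 0.215 with an estimated correlation) and the Calvin cycle genes -2.03 (camera adjusted p = 0.00121, and adjusted p = 0.215 with an estimated correlation). The adjusted p values of fry for these 3 lists were 0.309, 0.328 and 0.329. The Calvin cycle shift was lost without dor drought replicate 1 (median -0.62, adjusted p = 0.0590), dor control replicate 1 (median -1.61, adjusted p = 0.0582) or wild type control replicate 2 (median -1.51, adjusted p = 0.0831). Over both conditions dor and wild type differed at 0 probe sets in limma, with 308 at an unadjusted p under 0.05, where chance gives 776. The medians of the effector, photosystem and wall enzyme lists were 0.48, -0.43 and -1.08 there (camera adjusted p = 0.0430, 0.0224 and 0.0430, adjusted p = 0.526, 0.526 and 0.455 with an estimated correlation, and 0.731, 0.695 and 0.632 with fry). Without dor drought replicate 1 these 3 medians were 0.08, -0.15 and -0.49 (camera adjusted p = 0.546, 0.381 and 0.174), and with the replicate block the adjusted p values were 0.0862, 0.0501 and 0.0501. All 3 shifts were also lost with median centring, without the filter on low signal, and without wild type control replicate 1 or any 1 of the other drought arrays (adjusted p from 0.0510 to 0.240).

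The other lists with at least 3 tested members showed no shift past camera in either drought comparison. Their median drought differences in wild type and dor were 0.26 and -0.25 for 5 flavonoid and anthocyanin genes, 1.22 and 0.31 for 3 salicylic acid defence genes, and -0.54 and -0.00 for 4 antioxidant genes. In wild type the Calvin cycle genes had a median of -0.25 and the guard cell markers -0.22. Their camera adjusted p values lay between 0.123 and 0.801. For the flavonoid list in wild type camera ranked the genes lower although the median was positive. Within replicate 1 the flavonoid medians were -1.70 in wild type and -2.20 in dor, and within replicate 2 they were 0.90 and 3.08. Within replicate 1 the salicylic acid medians were 2.75 and 1.47, and within replicate 2 they were -0.30 and -0.92. The antioxidant medians were -1.43 and 0.26 within replicate 1 and 0.44 and -0.40 within replicate 2.

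Lists with 1 or 2 tested members were not tested as lists, and none of the members that follow passed the test in wild type or dor. The wild type and dor differences were -0.59 and -0.90 for BGLU33 of ABA synthesis, 2.93 and 3.13 for STZ of the drought transcription factors, and 3.62 and 3.43 for UGT71B6 of ABA catabolism. They were -0.60 and -2.49 for AT2G31790 and -1.01 and -2.06 for BCAT4, both of aliphatic glucosinolate synthesis, and 0.69 and 1.52 for WRKY6 of leaf senescence. For the heat shock list they were 3.25 and -1.12 for AT5G51440 and 2.18 and 2.57 for AT5G37670. They were -0.69 and -0.52 for the cell cycle gene AUR1, -1.52 and -1.07 for the wax gene WSD1, -0.92 and 1.67 for the clock gene GI, and -0.68 and -3.88 for the trichome gene TRY. The lists of ABA receptors, clade A PP2C phosphatases, SnRK2 kinases and ABF factors, proline and raffinose synthesis, jasmonate, aquaporins, phloem, xylem and flower markers had 0 tested members, because the annotation names none of their probe sets. Of the 8 root markers 2 had a named probe set, and these were not tested because of the filter on low signal. NCED3, which codes for an enzyme of ABA synthesis, was among the genes without a named probe set.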

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

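All tests in this part were chosen only after the result was seen, except the count of splits for the genotype comparison and that comparison with the replicate number as a block.

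The control probe set AFFX-Athal-Ubq_M_f_at, for the middle of a ubiquitin transcript, drew attention because it had a geometric mean signal of 11930 in the drought arrays (10157 to 17090) and 6166 in the control arrays (3689 to 8924), with no overlap. Of 64 control probe sets examined, chance puts 1.43% above in this way, or 0.914 of them. Its ratio to the 3 prime probe set, 0.430 to 0.632 in drought and 0.174 to 0.405 in control, contains the same signal and is no separate evidence. The 5 prime to 3 prime ratios of actin (0.370 to 0.497 in drought, 0.229 to 0.575 in control) and GAPDH (0.799 to 1.09 and 0.847 to 1.03) overlapped between the conditions. No explanation of the ubiquitin signal was tested.

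The 8 arrays were also split in 34 ways into 4 and 4 with the other factor kept in the model. For drought over both genotypes 1 of the 34 splits, the real one, gave as many as 902 calls, and the highest other split gave 2. This excludes chance only if the 8 arrays are independent, but arrays of one condition and replicate number deviated together. Only 3 splits keep such arrays together, too few for a share under 0.05, and of these 1, the real one, gave 902 calls and the highest other gave 1. With condition and replicate number as a random block 12 calls were left. For genotype over both conditions all 34 of 34 splits gave at least the 0 calls of the real one (308 probe sets at an unadjusted p under 0.05 in limma), as any split must, so this count says nothing about chance. The highest other split of the genotype comparison gave 209 calls and was the split by replicate number, which points to a structure of the samples. With the replicate number as a block the genotype comparison gave 0 calls in limma and 497 probe sets at an unadjusted p under 0.05.

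The drought differences were wider in replicate 1 than in replicate 2, with a standard deviation across probe sets of 1.89 against 1.29 in wild type and 2.31 against 1.296 in dor. Unequal signal distributions are argued against as the whole cause, since after quantile normalization the ratio of replicate 1 to replicate 2 was still 1.32 in wild type and 1.63 in dor. In wild type the watered plants of replicate 2 may already have expressed drought genes. The effector genes were higher there than in replicate 1 by a median of 2.28 log2 units (SD 2.08), with 7 of 8 higher. Among the 7, LEA18 read 1.2 and 5.6 in control replicates 1 and 2, under the 40th percentile of those arrays (59.5 and 89.4). Its rise therefore depends on background, and the count and the median include it. In dor the median difference of the effector genes between the controls was -0.31 (SD 1.96) with 4 of 8 higher. This leaves the explanation by drought genes in watered plants open there, since members go both ways. The deposited files hold no measure of soil or leaf water, so a difference in the drought itself between the replicates stays open and untested. RNA integrity or labelling of the controls of replicate 1 was not tested as a cause either. Their 5 prime to 3 prime actin ratio was 0.229 in wild type and 0.245 in dor, against 0.366 to 0.575 on the other arrays.

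The drought changes were larger in dor than in wild type along a shared axis, taken from the drought difference of the other replicate number. The ratio of dor to wild type was 1.48 and 1.44 in replicate 1 and 1.46 and 1.42 in replicate 2, depending on which genotype gave the axis. The lowest ratio in replicate 2 of 1.42 argues against replicate 1 alone as the cause, and the lowest ratio after quantile normalization, 1.45, against unequal signal distributions. No ratio has a measure of its spread, which limits what each can argue. Drought genes raised in watered wild type of replicate 2 are argued against as the only cause. The ratio was 1.44 in replicate 1 on the axis of dor replicate 2, which uses none of those arrays. Replicate 1 and these raised genes acting together stay open, since both ratios in replicate 2 use the watered wild type of replicate 2. Over all probe sets the standard deviations of the drought differences in replicate 2 were 1.29 in wild type and 1.296 in dor. The ratios of replicate 2 therefore reflect a closer match of dor than of wild type to the axis, and not wider changes over all probe sets. A larger response of the dor genotype and a harsher drying of the dor pots both stay open, since the probe sets are not independent, each genotype has 2 arrays per condition and the files hold no measure of pot water.

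The anthocyanin genes DFR, UF3GT and AT4G14090 were bright in both dor arrays of replicate 2, at 805, 537 and 419 in control and 6822, 7852 and 7264 in drought, while no other array exceeded 346. They stood above dor replicate 1 by a median of 6.29 log2 units over 6 differences, which ranged from 3.07 to 11.31. The largest puts a dor drought signal of replicate 1 under the 40th percentile of its array (61.5). The sizes of these differences therefore depend in part on background. The RNA extraction wording alone and the batch of replicate 2 alone are argued against by 1 difference in wild type, where the 2 split the arrays alike. Its median was 0.05003 for the wording and, with the sign turned, -0.05003 for the batch (SD 1.72). Wording and batch acting together in dor and against each other in wild type stay open, since the design does not separate this from a difference of the dor plants. The dor genotype alone is argued against by a difference from wild type of -1.06 (SD 1.78) in replicate 1. A condition particular to those dor plants, such as light or stress, and a mixed seed lot or label stay open, and no biological explanation was tested.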

How the results depend on the processing

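The random block and leaving out both controls of replicate 1 were chosen only after the results were seen, as was the drought comparison over both genotypes. Arrays of the 2 genotypes with one condition and replicate number deviated together from their group means (r = 0.402 under drought and 0.594 under control watering across probe sets), and arrays of different conditions did not (-0.04 to 0.05). With 2 replicate numbers this was not taken as pairing, and blocked counts are given beside. With the replicate block there were 1 call in wild type, 96 in dor, 0 in the 3 genotype comparisons in limma (127, 719 and 497 at an unadjusted p under 0.05) and 1682 over both genotypes. Calls for drought in wild type went from 1 to 3 with quantile normalization, 0 with median centring, 0 without the trend, 0 with the extraction block, 3 with only the 4 arrays compared, 0 without both controls of replicate 1, and 0 to 6 with 1 array left out. Calls in dor went from 88 to 153 with quantile normalization, 35 with the extraction block, 0 without both controls of replicate 1, and 0 to 108 with 1 array left out. Calls over both genotypes went from 902 to 387 with the extraction block, 12 with the random block, 12 without both controls, and 171 to 1543 with 1 array left out. The genotype difference under drought went from 0 to 22 calls with the random block, but stayed at 0 in limma with a fixed replicate block within condition (1617 at an unadjusted p under 0.05). The other genotype comparisons and the difference of the responses stayed at 0 calls in limma under every alternative run, with 29 to 1201 at an unadjusted p under 0.05. The 19 list shifts past camera fell to 0 with an estimated correlation and were 12 to 19 with 1 array left out. In the model of 4 group means the estimate was 0.36 for the effector, 0.78 for the photosystem and 0.86 for the Calvin cycle list. For the wall enzyme and guard cell lists it was -0.06 and -0.23, under the preset 0.01. A higher correlation between genes is therefore not what removed the shifts of these 2 lists. Leaving out 1 array turned these medians: effector genes in watered plants, dor against wild type (-2.03 to 0.49), cytosolic ribosomal genes in watered plants (-0.90 to 0.61), under drought (-0.42 to -0.0554, where only camera's direction turned) and over both conditions (-0.51 to 0.0718), plastid-encoded genes over both conditions (-0.46 to 0.00640) and in watered plants (-0.12 to 0.63), and guard cell markers for drought in dor (-0.96 to 0.00684). The cause was not tested, apart from the arrays left out. The median drought difference of all probe sets was 0.16 in wild type and 0.17 in dor, 0.05 in both with quantile normalization, and -0.13 to 0.39 and -0.11 to 0.38 with 1 array left out. Signals near background, such as those of DOR, limit what can be tested.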

Other observations

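All tests in this part were chosen only after the data were seen.

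The 8 tested genes for autophagy proteins, which recycle cell contents, are ATG3 and the 7 related genes ATG8B to ATG8H. Their group means were higher under drought in both genotypes, but no member was called in wild type or dor. ATG8E was lower under drought in wild type replicate 2 (391 against 541) and dor replicate 1 (1520 against 1741), and ATG8D in wild type replicate 2 (793 against 932). Their medians were 0.96 in wild type (camera adjusted p = 0.0456, and adjusted p = 0.628 with an estimated correlation) and 1.51 in dor (camera adjusted p = 0.0127, and adjusted p = 0.666 with an estimated correlation). The medians were 1.39 and 0.47 in wild type within replicates 1 and 2, and 1.75 and 0.90 in dor. With fry their adjusted p was 0.469 and 0.194. ATG8B rose over both genotypes by 1.61 ± 0.35 (adjusted p = 0.0335), a call that was lost with condition and replicate number as a random block.

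The ATG genes were one of 34 symbol families tested. The others past camera in wild type drought were EXPA (expansins) with a median of -1.23 (adjusted p = 0.0288), GH with -1.78 (adjusted p = 0.0456), RALFL with -1.43 (adjusted p = 0.0456) and SCPL with -0.68 (adjusted p = 0.0288). With an estimated correlation all 4 had an adjusted p of 0.628. In dor drought EXPA had a median of -2.50 (adjusted p = 0.00230, and adjusted p = 0.512 with an estimated correlation). GSTU, glutathione transferases, had -2.49 (adjusted p = 0.0270), IQD -1.53 (adjusted p = 0.0270), PDF -1.51 (adjusted p = 0.0455) and TBL -1.37 (adjusted p = 0.0455). With an estimated correlation these 4 had an adjusted p of 0.666. For dor against wild type under drought EXPA and GSTU had medians of -1.64 and -1.10 (camera adjusted p = 0.0193 and 0.0157, and adjusted p = 0.923 for both with an estimated correlation). For the difference of the responses GSTU and PDF had -1.54 and -1.66 (camera adjusted p = 0.00373 and 0.0276, and adjusted p = 0.911 for both with an estimated correlation). Among the families in this paragraph fry passed for EXPA in dor drought (adjusted p = 0.00808) and for no other of these comparisons (adjusted p = 0.0569 to 0.997).

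Genes for cytosolic ribosomal proteins differed between the watered replicates as well as between the conditions. The difference between the replicates was the smaller in wild type and the larger in dor, and no test compared them. For control replicate 2 minus replicate 1 the median of these genes was -1.12 in wild type and -1.50 in dor, and the controls of replicate 1 are the arrays with the low actin ratio. For drought over 110 genes the median was -1.30 in wild type, where 102 were negative (camera adjusted p = 1.83e-21, and adjusted p = 0.339 with an estimated correlation). It was -1.38 in dor, where 106 were negative (camera adjusted p = 2.27e-17, and adjusted p = 0.209 with an estimated correlation). With fry the adjusted p was 0.245 and 0.129. No member was called in either genotype. Over both genotypes 14 were called, and all 14 calls were lost with the random block. Their medians within replicates 1 and 2 were -1.87 and -0.66 in wild type and -1.85 and -0.84 in dor. The 69 plastid-encoded genes had a median of -0.02 in wild type (camera adjusted p = 0.513) and -0.83 in dor (camera adjusted p = 2.51e-07, and adjusted p = 0.209 with an estimated correlation). Their difference between the responses was -0.81, with 65 of 69 negative (camera adjusted p = 2.33e-10, adjusted p = 0.144 with an estimated correlation and 0.479 with fry). Within replicates 1 and 2 the plastid-encoded medians were 0.07 and -0.08 in wild type drought, -1.08 and -0.42 in dor drought, and -1.09 and -0.04 for dor against wild type under drought. The wild type median of the plastid-encoded genes was 0.10 with quantile normalization and -0.18 with median centring.

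With condition and replicate number as a random block, 22 probe sets were called between dor and wild type under drought, and 21 were lower in dor. With a fixed block of replicate number within condition limma called 0, with 1617 at an unadjusted p under 0.05. Among the 9 with 1 named gene were AT1G06830 (-5.59 ± 0.56, adjusted p = 0.0255), AT5G22580 (-5.47 ± 0.61, adjusted p = 0.0291) and IQD22 (-3.90 ± 0.45, adjusted p = 0.0295), a member of a family of calmodulin-binding proteins. IQD22 was at 8.4 and 10.7 in dor drought and 152 and 132 in wild type drought. These genes were chosen after their values were seen. Their dor drought signals lay under the 40th percentile of the arrays, so the sizes depend on background.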
